A study of Mus musculus with 4 samples.

How the data were processed

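The data were RNA sequencing counts of mouse cortical astrocyte cultures, 2 wild-type and 2 Npas3-/- samples of the C57BL/6 strain. Per the labels' protocols, newborn cortex was dissociated with papain, non-astrocytic cells were shaken off over the first week of culture, the cells were replated, and RNA was extracted with TRIzol at day 14 in vitro before Illumina library construction from total RNA. How RNA was selected and whether the libraries kept strand are not given in the sources used here. The authors deposited a single table of raw counts per gene for the 4 samples, with Ensembl gene identifiers. Per the submitters' processing notes, Trimmomatic 0.3.8, HISAT2 2.1.0, featureCounts and the genome build mm10 were used. The featureCounts version, the annotation release, the strand setting and the handling of reads shared between genes are not given in the sources used here. Reads shared by overlapping genes or near-identical copies could therefore be lost, split or counted in either, and the counts of such genes are uncertain.

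Columns were matched to samples by their names and the sample titles, and groups were taken from the genotype label. The labels do not say whether the 2 samples of a genotype came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Symbols, coordinates, transcript lengths and GC content came from the GENCODE annotation and sequence of the same mouse build, in which 53274 of 53379 identifiers were found. For each gene the longest protein-coding transcript was used, or the longest transcript where there was none, and 99.9% of tested genes had a GC content and length.

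Total counts were between 82965565 and 86932708 per sample, so that depth differed little between genotypes. Shares of counts in a single library were given Wilson 95% intervals. Folds against a genotype at 0 counts in both libraries were computed against a floor of 3 counts per library, and intervals and floors cover counting error only.

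Tests, gene lists, the rule for named genes and all alternatives not said to be added later were fixed before the data were examined. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM normalization and filterByExpr at its default minimum count of 10. It compared the 2 genotypes over the 4 samples with no covariate, leaving 2 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 CPM for principal components and correlations had a pseudocount of 2. CPM were computed over TMM-scaled library sizes, and the SE of a log2 fold change is its size over the square root of the test's F value. Gene lists, 29 in all and named with their results in the report, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, with an estimated correlation and fry as alternatives. With an estimated correlation camera uses the 2 residual degrees of freedom, so it could hardly call any list here. Genes around Npas3 were compared by a two-sided Fisher's exact test within a window of 20 Mb.

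The genes named were Npas3, the 8 with the largest rise and the 8 with the largest fall among genes past the threshold with at least 5 CPM on average, no overlap between genotypes and a symbol that is not a model or clone name, and in each list the 3 tested members with the smallest p-value. For lists of other cell types the most abundant tested member was added, and the sex-linked genes were given as counts. Single-gene values of 2 genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

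The alternatives were DESeq2 size factors, no filter on low counts, a filter of 5 CPM on average, the replicate number as a block, leaving out each sample in turn, DESeq2 1.42.0, limma-voom, an adjusted p below 0.01, a test against a fold of 1.5, windows of 5 Mb and of the whole chromosome, and the 500 most variable genes. After the data were seen, a correction for GC content and length was added: per library, a natural spline with 6 degrees of freedom in each of GC content and log2 length was fitted to the deviation of log2 CPM from the gene's mean and entered as an offset. Such a correction also removes any true difference that follows GC content or length. A crossed replicate block was added too.

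The tests were tested on simulated data, with counts drawn for the real genes and 200 genes changed. Without a GC trend, over 18201 genes, edgeR called 5 of 18001 unchanged genes and recovered 6.00% of genes changed 1.5-fold, 30.0% at 2-fold, 88.0% at 4-fold and 98.0% at 8-fold, of 50 each. With a GC trend between genotypes in the simulation, over 17886 genes, it called 6667 of 17686 unchanged genes (37.7%), and with the correction 5, while the correction recovered 26.0% of the 2-fold and 94.0% of the 4-fold changes. Camera called 3 of 29 lists in the simulation with the GC trend, and 0 with the correction or without the trend. The simulated trend was linear in GC content and alike in both Npas3-/- libraries, with no trend in length or within genotypes. Genes were drawn independently, so the simulation does not show how well the correction works on the real libraries. Changed genes were taken from those with at least 1 CPM. Counts were drawn at the trended dispersion of the fit with the correction, without further spread between genes. The common biological coefficient of variation was 0.337 in that fit and 0.391 in the main fit, so recovery in the real libraries may be lower. Within genotypes the counts of the 2 libraries differed far beyond sampling noise, with a chi-square per degree of freedom of 277 for wild type and 156 for Npas3-/-, so that no library was counted as a duplicate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.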

Results

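RNA-seq gene counts were deposited for cortical astrocytes of 2 genotypes, wild type and Npas3-/-, with 2 samples each. Npas3 encodes a bHLH-PAS transcription factor of neural cells, and the comparison asks which transcripts differ between astrocytes of the 2 labelled genotypes. The cells came from newborn C57BL/6 mouse cortex and were taken at day 14 in vitro. The 4 libraries held 82965565 (wild-type replicate 1), 85688472 (wild-type replicate 2), 86932708 (Npas3-/- replicate 1) and 85897778 (Npas3-/- replicate 2) counts over genes. Of 53379 genes in the table, 27026 had a count in at least 1 sample and 18838 were tested. Genes with a count numbered 22902 and 23761 in wild-type replicates 1 and 2, and 20652 and 21337 in Npas3-/- replicates 1 and 2. Of the tested genes 329 stood at 0 in both Npas3-/- libraries and 30 in both wild-type libraries. Lhfpl3, Tek and Gm20716, given below, are among the 329. Of the 329, 22 had at least 50 counts in both wild-type libraries, Gm20716 among them. Values below are means ± SD of n = 2 samples per genotype in CPM (counts scaled to library size), and a positive log2 fold change means higher in Npas3-/-.

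Npas3 itself (ENSMUSG00000021010.8, mm10 chromosome 12, 53248677 to 54072175, plus strand) was lower in both Npas3-/- libraries, with 2055 and 1386 counts against 5129 and 8739 in wild type. Its level fell from 75.6 ± 25.2 to 21.4 ± 4.81 CPM, a log2 fold change of -1.82 (SE 0.33; adjusted p = 0.0181, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Npas3-/- libraries thus kept 28.3% of the wild-type level. It is overlapped by 2 other annotated genes, and reads shared with them are uncertain. The counts cover the whole gene, so a loss confined to deleted exons is not seen in them, and they do not settle whether the libraries labelled Npas3-/- lack the gene's function. Without Npas3-/- replicate 2 the log2 fold change was -1.60 (adjusted p = 0.101, the same edgeR test and adjustment), and with a correction for transcript GC content and length, added after the data were seen, it was -0.66 (SE 0.21; adjusted p = 0.107 by edgeR's quasi-likelihood test).

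Across the transcriptome, 6232 genes changed at an adjusted p below 0.05 (33.1% of those tested), 2188 higher and 4044 lower in Npas3-/-. A change of at least 2-fold was seen for 1431 of the higher and 3822 of the lower genes. The 2 genotypes did not overlap for 75.8% of the tested genes, where chance gives 33.3%. The first principal component held 74.0% of the variance and separated the genotypes. Pearson correlations of log2 CPM across genes were 0.958 within wild type and 0.961 within Npas3-/-, and 0.854 to 0.929 between genotypes. Genes are not independent replicates in these correlations. The count rested on individual libraries: it was 2991 without wild-type replicate 2, 2425 without Npas3-/- replicate 1 and 0 without Npas3-/- replicate 2. In that last fit edgeR's quasi-likelihood test gave 5728 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.0798, DESeq2 called 3635 genes and limma-voom 0.

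The fold changes followed the composition of the transcripts. Among 14356 genes with at least 1 CPM, the log2 fold change correlated with transcript GC content (Spearman's rho 0.730 across genes) and with length (rho -0.484). Transcripts with under 38% GC had a median log2 fold change of -2.59 over 201 genes, and those with over 58% GC a median of 0.87 over 1659 genes. The libraries of the same genotype differed along the same gradient, with a rho on GC of 0.535 for wild-type replicate 1 minus 2 and 0.359 for Npas3-/- replicate 2 minus 1. The count-weighted GC content was 51.5% and 50.2% in wild-type replicates 1 and 2, and 53.2% and 53.6% in Npas3-/- replicates 1 and 2. With the correction for GC and length, 1621 genes changed, 845 higher and 776 lower, and 1062 genes were called in the same direction with and without it (360 higher and 702 lower). This corrected count was 0 without Npas3-/- replicate 1, where edgeR's quasi-likelihood test gave 4549 genes at an unadjusted p below 0.05 and DESeq2 called 2174. It was 997 without wild-type replicate 2 and 5 without Npas3-/- replicate 2, so each gene list below is given with its corrected counts too.

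**Figure D1:**
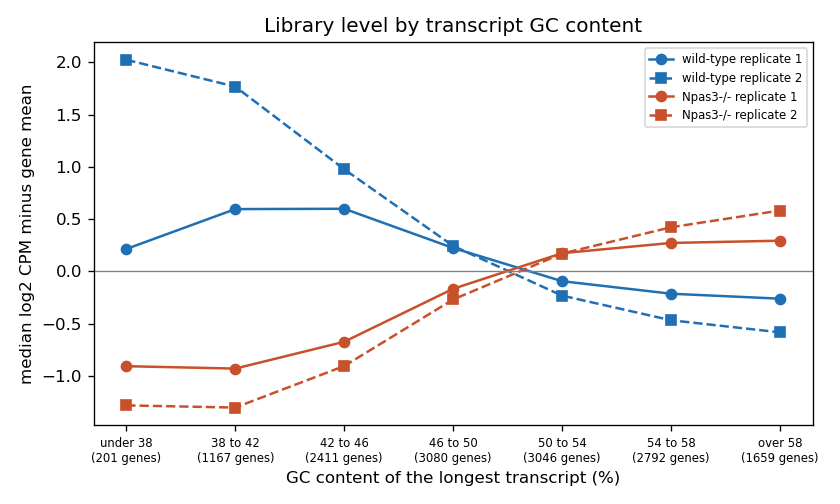
Median log2 CPM minus the gene's mean over the 4 libraries (y axis) for genes binned by transcript GC content in percent (x axis, genes per bin in brackets), with a line per library. Below 38% GC wild-type replicate 2 stood at 2.02 and wild-type replicate 1 at 0.21, against -0.91 and -1.28 in the Npas3-/- replicates, and above 58% GC the order was turned round.

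Transcripts of the mitochondrial genome were lower in Npas3-/-. Their messenger RNAs made up 1.68% and 3.10% of the counts in wild-type replicates 1 and 2, and 0.578% and 0.365% in Npas3-/- replicates 1 and 2. Wilson 95% intervals of these shares and of those of genes with Rpl or Rps symbols reached at most 0.00417 percentage points to either side, which covers counting error only. Of the 13 mitochondrial protein genes 12 fell and 0 rose (13 fell when adjusted over the list alone), with a median log2 fold change of -2.79. The respiratory chain subunit genes mt-Nd3, mt-Co2 and mt-Co3 fell from 122 ± 30.7 to 13.1 ± 1.70 CPM, from 1729 ± 478 to 390.2 ± 46.2 CPM and from 1361 ± 576 to 197 ± 37.1 CPM. As a list they fell against the other genes (camera with preset correlation, adjusted p = 1.63e-08; adjusted p = 0.944 with an estimated correlation). These transcripts have a median GC content of 37.1%, and with the GC and length correction the median was -1.26 and 6 of 13 fell (10 when adjusted over the list alone). The list was called again there (adjusted p = 3.55e-06 by camera with preset correlation, and 0.852 with an estimated correlation). In a check added after the data were seen, each gene was set against the 200 nuclear genes nearest in GC content and length. Those had a median GC content between 39.1% and 45.1%, above that of the list. The fold changes lay at percentiles between 2 (mt-Nd4l) and 71 (mt-Nd2), with mt-Co1, the most abundant, at 45. The library trend may therefore account for the fall of many of these genes.

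The largest rise among genes that met the naming rule was that of Bc1 (ENSMUSG00000115783.1, mm10 chromosome 7, 144914470 to 144914637), a short non-coding RNA known from neuronal dendrites. It rose from 0.166 ± 0.0992 to 31.3 ± 15.5 CPM, with 21 and 9 counts in wild type and 1685 and 3251 in Npas3-/-, a log2 fold change of 7.55 (SE 0.68). Next came Ramp2, a receptor activity-modifying protein gene (from 1.41 ± 0.172 to 14.8 ± 10.8 CPM), the adrenoceptor gene Adra2c (from 1.25 ± 0.302 to 10.9 ± 2.08 CPM), the Wnt receptor gene Fzd9 (from 3.11 ± 0.528 to 23.04 ± 4.45 CPM) and the homeobox gene Nkx6-2 (from 13.0 ± 6.79 to 96.1 ± 36.7 CPM). The acute-phase gene Saa3 rose from 3.08 ± 0.862 to 20.4 ± 8.61 CPM, the protease inhibitor gene Cst3 from 756 ± 37.2 to 4266 ± 721 CPM and the interferon-inducible Ifi27l2a from 20.9 ± 2.36 to 117 ± 19.0 CPM. The 8 adjusted p-values lay between 0.0130 and 0.0190 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the GC and length correction 7 of the 8 passed again, and Ramp2 had a log2 fold change of 2.08 (adjusted p = 0.0521, edgeR's quasi-likelihood test).

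The largest falls among genes that met the naming rule were those of Ap3m1, which encodes an adaptor complex subunit (from 125 ± 45.2 to 3.65 ± 0.00284 CPM, log2 fold change -5.09, SE 0.35), and of the membrane glycoprotein gene Gpm6a (from 133 ± 51.2 to 4.72 ± 0.501 CPM, log2 fold change -4.81, SE 0.36). Ap3m1 overlaps Vcl in the annotation, so its counts are uncertain where reads were shared. The inflammatory caspase gene Casp1 fell from 11.7 ± 4.91 to 0.511 ± 0.0797 CPM, the AMPA receptor subunit gene Gria2 from 54.3 ± 38.7 to 2.54 ± 0.727 CPM and the phospholipase gene Pla2g4a from 28.03 ± 16.4 to 1.36 ± 0.132 CPM. Acss3, Mier1 and Samd12 fell from 9.85 ± 7.35 to 0.407 ± 0.0299 CPM, from 39.2 ± 24.9 to 1.89 ± 0.132 CPM and from 21.7 ± 14.0 to 1.06 ± 0.582 CPM. The 8 adjusted p-values lay between 0.0130 and 0.0155 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). All 8 transcripts had a GC content of at most 42.1%, and all 8 passed again with the GC and length correction, at log2 fold changes between -3.003 and -1.50.

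Astrocyte markers went both ways. Of 24 tested, 6 rose and 5 fell (8 and 6 adjusted over the list alone), with a median log2 fold change of 0.089 and a mean of -0.12. The gap junction gene Gja1 fell from 200.2 ± 39.3 to 33.4 ± 6.28 CPM, while Cst3 and the glycolytic gene Aldoc rose, Aldoc from 317 ± 80.6 to 1482 ± 52.3 CPM. With the correction 4 rose and 4 fell, and Gja1 (log2 fold change -1.41), Cst3 (1.33) and Aldoc (1.93) passed again. Among 24 genes of glutamate, GABA and potassium handling 1 rose and 10 fell (2 and 12 adjusted over the list alone). The potassium channel gene Kcnj10 fell from 459 ± 97.4 to 93.7 ± 32.5 CPM, Gria2 as given above, and the chloride transporter gene Slc12a2 from 86.8 ± 27.3 to 19.3 ± 0.968 CPM. Camera gave an adjusted p of 0.0658 for this list, the median log2 fold change was -0.88, and the median GC content was 48.5%. With the correction the median was -0.22, 4 rose and 5 fell, and the log2 fold change was -1.75 for Kcnj10, which passed, and -0.19 for Slc12a2, which did not.

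Neural progenitor genes included strong falls. Of 16 tested 0 rose and 4 fell, also when adjusted over the list alone. Fabp7 (chromosome 10, 57784881 to 57788450), the brain fatty acid binding protein gene of radial glia, fell from 779.8 ± 211 to 38.9 ± 8.06 CPM, a log2 fold change of -4.32 (SE 0.32). The receptor phosphatase gene Ptprz1 fell from 259 ± 151 to 37.5 ± 13.3 CPM. The list had a camera adjusted p of 0.254 and a median log2 fold change of -0.23. With the correction it was called as lower (adjusted p = 0.00469 by camera, median log2 fold change -0.49; adjusted p = 0.852 with an estimated correlation), with 3 members falling. Fabp7 stood at -3.17 in that fit and passed, and Ptprz1, at -0.75, did not pass.

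**Figure D2:**
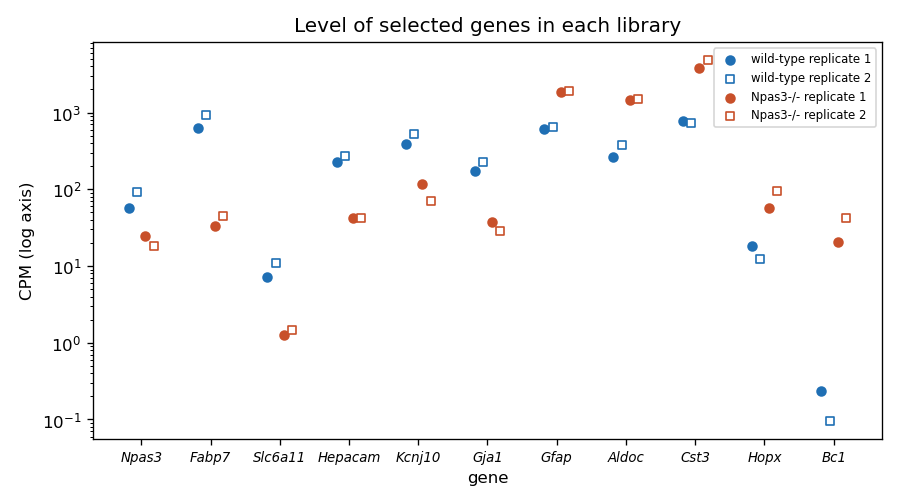
CPM of 11 genes (log axis) in each of the 4 libraries, with filled circles for replicate 1 and open squares for replicate 2, wild type in blue and Npas3-/- in red. Npas3, Fabp7, Slc6a11, Hepacam, Kcnj10 and Gja1 are lower and Gfap, Aldoc, Cst3, Hopx and Bc1 higher in both Npas3-/- libraries than in both wild-type libraries.

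Of 28 regulators of astrogliogenesis 2 rose and 11 fell (3 and 12 adjusted over the list alone). Smad5, a mediator of BMP signals, fell from 97.4 ± 16.1 to 21.5 ± 2.76 CPM, the nuclear factor gene Nfib from 187 ± 63.3 to 28.4 ± 6.95 CPM and the inhibitor of differentiation gene Id2 from 152 ± 15.6 to 33.4 ± 11.4 CPM. With the correction 2 rose and 1 fell: Id2 stood at -1.33 and passed, while Smad5 (-0.36) and Nfib (-0.41) did not. Of 26 astrocyte-secreted regulators of synapses 5 rose and 6 fell, also over the list alone. Lcat rose from 63.5 ± 4.16 to 184 ± 5.84 CPM and Ptx3 from 98.3 ± 16.5 to 274 ± 56.0 CPM, and the alarmin gene Il33 fell from 8.52 ± 0.318 to 1.74 ± 0.308 CPM. With the correction 2 rose and 1 fell. Ptx3 (1.14) passed there, and Lcat (0.57) and Il33 (-0.77) did not.

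Genes of reactive astrocytes were held in 3 lists. In the pan-reactive list 4 of 13 rose and 2 fell (4 and 3 adjusted over the list alone), among them Gfap, the intermediate filament gene of astrocytes, which rose from 634 ± 30.0 to 1885 ± 20.5 CPM, with Hspb1 (from 30.8 ± 6.99 to 78.9 ± 10.2 CPM) and Aspg (from 1.10 ± 0.243 to 5.03 ± 0.828 CPM). The A1-type list had 5 of 12 higher and 1 lower, the same over the list alone, with H2-T23, H2-D1 and Psmb8, genes of antigen presentation, rising from 59.7 ± 14.9 to 241 ± 30.8 CPM, from 414 ± 33.7 to 1204 ± 260.2 CPM and from 68.8 ± 1.88 to 226 ± 78.0 CPM. Its camera adjusted p was 0.0658, and with the correction, where 3 rose and 0 fell, it was called as higher (adjusted p = 0.00469 by camera, median log2 fold change 0.73; adjusted p = 0.852 with an estimated correlation). None of H2-T23, H2-D1 and Psmb8 passed in that fit, with corrected edgeR adjusted p between 0.0519 and 0.0734, while Gfap passed with a log2 fold change of 0.93. In the A2-type list 3 of 11 rose and 3 fell (4 and 4 adjusted over the list alone), with Tm4sf1 rising from 134 ± 15.5 to 585 ± 21.2 CPM and Ptgs2, the inducible cyclooxygenase gene, falling from 9.62 ± 3.97 to 1.17 ± 0.0454 CPM, and with the correction 2 rose and 1 fell. Tm4sf1 passed there at a log2 fold change of 3.74, and Ptgs2, at -0.76, did not. The pan-reactive list had 1 higher and 0 lower in the corrected fit. Beside these lists, microglia and macrophage markers, near the limit of detection, had a median log2 fold change of 1.69 without a list call.

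Inflammatory genes were split. Of 23 interferon-stimulated genes 8 rose and 7 fell (8 and 8 adjusted over the list alone): Oas1a rose from 38.7 ± 3.32 to 112 ± 10.1 CPM, Irf7 from 31.7 ± 5.63 to 85.4 ± 14.2 CPM and Isg15 from 127 ± 1.98 to 338 ± 82.9 CPM. With the correction 2 rose and 0 fell, and Oas1a, at 0.97, passed. Among 18 NF-kB cytokines and adhesion molecules 1 rose and 4 fell, also over the list alone: the chemokine genes Ccl7 and Ccl2 fell from 11.1 ± 3.95 to 1.30 ± 0.278 CPM and from 63.0 ± 34.3 to 12.7 ± 3.96 CPM, and Saa3 rose. With the correction 1 rose and 1 fell. Of 20 genes of phagocytosis and complement 3 rose and 8 fell, also over the list alone, with Gas6 rising from 779 ± 55.0 to 2263 ± 212 CPM and Dock1 and the cholesterol exporter gene Abca1 falling from 116 ± 12.7 to 39.5 ± 5.84 CPM and from 600.1 ± 190.1 to 111 ± 33.8 CPM. In the corrected fit 1 rose and 1 fell. Abca1 (-1.08) passed there, and Gas6 (0.80) and Dock1 (-0.62) did not.

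Glycolysis and hypoxia genes rose against the other genes as a list (camera with preset correlation, adjusted p = 0.00723; adjusted p = 0.944 with an estimated correlation). The call ended with a filter of 5 CPM on average too, at an adjusted p of 0.0627 by camera, and over all alternatives this p lay between 6.81e-04 and 0.944. Of 25 tested 7 rose and 2 fell (9 and 3 adjusted over the list alone), with a median log2 fold change of 0.61. Ndrg1 rose from 283 ± 95.02 to 1059 ± 22.9 CPM and the prolyl hydroxylase gene Egln3 from 35.1 ± 9.16 to 124 ± 2.48 CPM, while Bnip3, a mitophagy gene, fell from 37.7 ± 9.02 to 13.1 ± 1.40 CPM. The list's median GC content was 52.8%, and with the correction its median log2 fold change was 0.21, 3 rose, 1 fell, and camera gave an adjusted p of 0.0709. Ndrg1 (1.61) and Egln3 (1.59) passed there and Bnip3 (-0.060) did not. Among 22 genes of cholesterol synthesis 1 rose and 6 fell (4 and 8 adjusted over the list alone), with Sc5d, Hsd17b7 and Hmgcs1 falling from 60.5 ± 7.58 to 12.7 ± 0.459 CPM, from 27.1 ± 2.44 to 5.54 ± 0.483 CPM and from 128 ± 9.26 to 43.5 ± 5.12 CPM. None of these 3 passed with the correction, Hmgcs1 stood at 0.083 there, and 1 of the 22 rose and 0 fell.

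Genes linked to autism fell as a list (camera with preset correlation, adjusted p = 9.61e-06; adjusted p = 0.944 with an estimated correlation). Of 31 tested 0 rose and 18 fell (20 fell when adjusted over the list alone), with a median log2 fold change of -1.46. The extracellular guidance gene Reln fell from 7.73 ± 0.355 to 0.321 ± 0.0608 CPM, the chromatin remodeller gene Chd8 from 90.9 ± 6.29 to 29.1 ± 8.73 CPM and the NMDA receptor subunit gene Grin2b from 7.24 ± 4.44 to 0.664 ± 0.0521 CPM. The members are long, with a median transcript of 8737 nt. With the correction the median was -0.58, 1 rose and 7 fell, among them Reln and Chd8, and the list was called again (adjusted p = 0.0145 by camera; adjusted p = 0.852 with an estimated correlation). Of 30 genes of axon guidance and contact signalling 4 rose and 14 fell (6 and 15 adjusted over the list alone), with Epha4, Efnb2 and the semaphorin receptor gene Nrp1 falling from 75.9 ± 10.0 to 13.5 ± 3.40 CPM, from 179 ± 24.0 to 48.9 ± 8.43 CPM and from 50.9 ± 12.3 to 13.3 ± 1.96 CPM. Their median log2 fold change of -1.20 became 0.20 with the correction, where 1 rose and 4 fell and Epha4, Efnb2 and Nrp1 passed.

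Among 22 circadian and bHLH-PAS genes 1 rose and 6 fell, also over the list alone. Npas1, a paralogue of Npas3, fell from 7.61 ± 0.0183 to 1.39 ± 0.0875 CPM, the clock gene Arntl fell from 21.9 ± 0.377 to 5.95 ± 0.851 CPM, and the clock output gene Dbp rose from 71.4 ± 7.19 to 165 ± 15.3 CPM. With the correction 0 rose and 3 fell, Npas1 at a log2 fold change of -3.47 (SE 0.38) and Arntl at -1.38. Of 18 genes of FGF signalling 1 rose and 5 fell (2 and 5 adjusted over the list alone): Fgfr2, Frs2 and Spred1 fell from 147 ± 3.71 to 57.5 ± 5.91 CPM, from 67.3 ± 16.8 to 16.5 ± 3.26 CPM and from 169 ± 69.8 to 37.5 ± 6.54 CPM. With the correction 1 rose and 2 fell, Fgfr2 passed at -1.03, and Spred1 stood at 0.23. Of 26 cell cycle genes 0 rose and 7 fell, also over the list alone, Top2a from 217 ± 56.4 to 30.1 ± 5.10 CPM, Ccnb1 from 82.7 ± 8.32 to 28.7 ± 1.78 CPM and Pcna from 108 ± 19.8 to 36.6 ± 5.14 CPM. Log2 fold changes of the cell cycle list were positive for 13 genes and negative for 13, with a median of -0.013. The list was not called (adjusted p = 0.522 by camera). With the correction 2 rose and 1 fell, the latter Top2a at -0.89.

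Extracellular matrix genes had 6 of 30 higher and 10 lower (7 and 10 adjusted over the list alone), with Col8a1, Adamts5 and Lama2 falling from 201 ± 28.2 to 60.6 ± 2.15 CPM, from 24.0 ± 2.04 to 6.40 ± 0.0831 CPM and from 48.6 ± 4.62 to 15.4 ± 3.88 CPM. With the correction 2 rose and 3 fell, none of those 3 genes passed, and Adamts5 stood at 0.38. Of 22 immediate early and stress genes 5 rose and 0 fell, also over the list alone, among them Ier3 (from 61.0 ± 6.09 to 163 ± 20.5 CPM) and the near-identical heat shock genes Hspa1a (from 13.2 ± 2.24 to 38.7 ± 8.13 CPM) and Hspa1b (from 12.5 ± 1.91 to 32.2 ± 7.13 CPM), whose reads may have been split between the copies. With the correction 1 rose and 1 fell, and the list's median log2 fold change went from 0.46 to -0.036. Ier3 (0.47), Hspa1a (0.84) and Hspa1b (0.64) did not pass there. In the p53 and senescence list 3 of 15 rose and 5 fell (4 and 5 adjusted over the list alone), with Eda2r, Mdm2 and Ccng1 falling from 111 ± 36.2 to 10.6 ± 3.64 CPM, from 153 ± 43.4 to 35.3 ± 2.51 CPM and from 644 ± 514 to 71.7 ± 13.3 CPM, and with the correction 0 rose and 2 fell, Eda2r and Mdm2. Of 16 genes of regional identity 1 rose, Dmrta2 (from 32.9 ± 8.90 to 106 ± 42.8 CPM), and 1 fell, Dlx2 (from 15.6 ± 2.096 to 6.42 ± 0.951 CPM), also over the list alone. Dlx1 stood at 6.89 ± 3.68 CPM in wild type and 2.19 ± 0.573 CPM in Npas3-/- and did not pass. With the correction 0 rose and 2 fell, among them Dlx2 at -2.098.

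**Figure D3:**
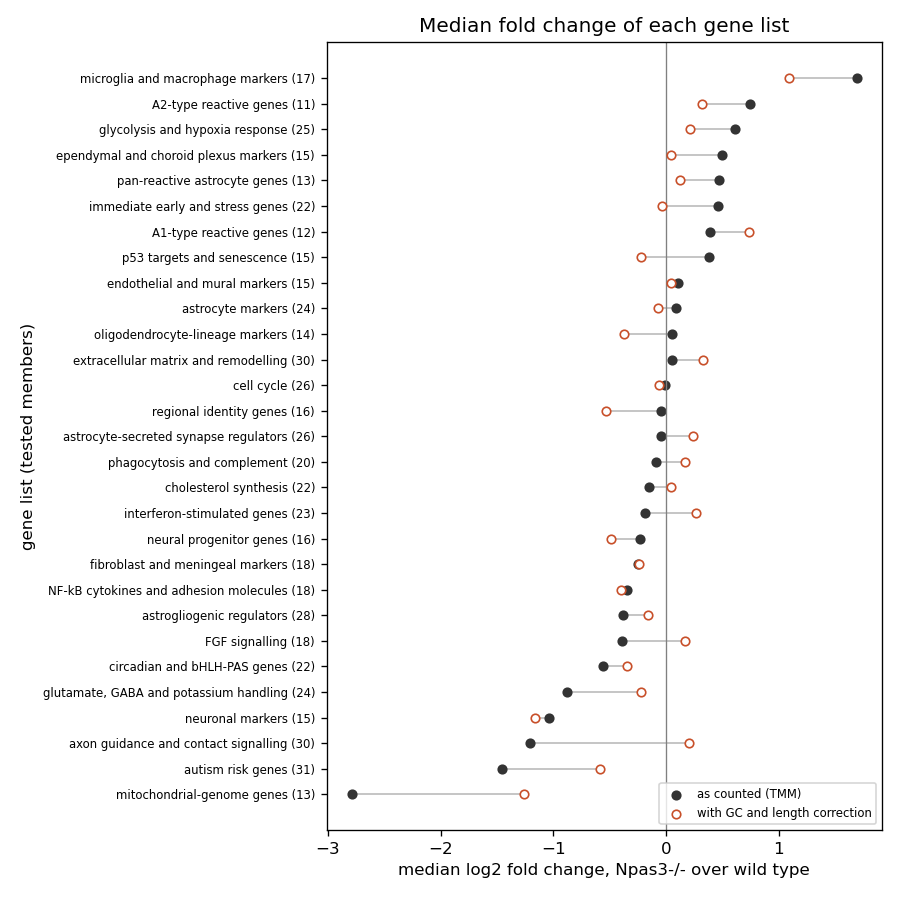
Median log2 fold change of the tested members of each of the 29 gene lists (x axis, Npas3-/- over wild type, with the number of tested members in brackets on the y axis), as counted (filled points) and with the GC and length correction (open points). The mitochondrial-genome genes moved from -2.79 to -1.26 and the axon guidance genes from -1.20 to 0.20.

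Markers of other cell types went both ways. Of 15 neuronal markers 1 rose and 4 fell (2 and 6 adjusted over the list alone): Map2 fell from 40.7 ± 6.07 to 3.12 ± 1.85 CPM, Gad2 from 3.98 ± 0.309 to 0.409 ± 0.0831 CPM and Syt1 from 4.30 ± 1.26 to 0.788 ± 0.251 CPM, and Stmn2, the most abundant, stood at 154 ± 90.4 CPM in wild type and 121 ± 8.99 CPM in Npas3-/- without passing. With the correction 0 rose and 2 fell, and Map2 was among them at -2.72. Of 14 oligodendrocyte-lineage markers 1 rose and 2 fell (0 and 0 adjusted over the list alone). Cnp rose from 246 ± 24.7 to 416 ± 55.8 CPM, and Lhfpl3, with 58 and 36 counts in wild type and 0 in both Npas3-/- libraries, was at least 13.8-fold lower against a floor of 3 counts per library. Olig1, the most abundant, stood at 1046 ± 45.5 CPM in wild type and 1279.8 ± 229.6 CPM in Npas3-/-. With the correction 0 rose and 1 fell. Neither Cnp (0.018) nor Lhfpl3 (adjusted p = 0.0787, edgeR's quasi-likelihood test) passed there.

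Microglia and macrophage markers were near the limit of detection. The median of 17 tested was 0.203 CPM in wild type, and 1 rose, Cyth4 (from 0.308 ± 0.0735 to 1.52 ± 0.0344 CPM). Adjusted over the list alone 0 rose and 0 fell, and with the correction edgeR's quasi-likelihood test called 0 of the 17. Of these markers 14 had a positive log2 fold change, with a median of 1.69, or 1.09 with the correction, and the list was not called (adjusted p = 0.0765 by camera; adjusted p = 0.944 with an estimated correlation). Its direction turned with a filter of 5 CPM on average (adjusted p = 0.914 by camera), but of these markers only Cd68 passed that filter. The turn therefore rests on a single gene and says nothing about the other markers. Laptm5 stood at 0.824 ± 0.380 CPM in wild type and 2.64 ± 0.128 CPM in Npas3-/-, Trem2 at 0.0492 ± 0.00592 CPM in wild type and 0.438 ± 0.252 CPM in Npas3-/- and Cd68, the most abundant, at 7.41 ± 1.42 CPM in wild type and 5.47 ± 1.07 CPM in Npas3-/-, none of which passed. Of 15 endothelial and mural markers 0 rose and 2 fell, also over the list alone: Rgs5 fell from 7.64 ± 5.41 to 0.349 ± 0.0527 CPM, and Tek, with 36 and 49 counts in wild type and 0 in both Npas3-/- libraries, was at least 12.4-fold lower. Notch3 stood at 214 ± 26.9 CPM in wild type and 133 ± 22.4 CPM in Npas3-/- and Acta2, the most abundant, at 757 ± 688 CPM in wild type and 1347 ± 17.5 CPM in Npas3-/-, and with the correction 1 fell. Of 18 fibroblast and meningeal markers 2 rose and 5 fell, also over the list alone, with Islr rising from 819.9 ± 60.8 to 1967 ± 73.8 CPM and Col3a1 and Aldh1a2 falling from 24.3 ± 7.62 to 6.36 ± 0.701 CPM and from 3.11 ± 0.241 to 0.575 ± 0.00563 CPM. With the correction 0 rose and 3 fell, among them Col3a1 and Aldh1a2. Of 15 ependymal and choroid plexus markers 3 rose, Pifo (from 2.35 ± 0.119 to 5.71 ± 0.0212 CPM), Mia (from 2.29 ± 1.16 to 7.48 ± 0.684 CPM) and Rarres2 (from 20.5 ± 0.485 to 37.7 ± 7.68 CPM), and 0 fell, but 0 passed over the list alone. Foxj1, the most abundant, stood at 292 ± 72.9 CPM in wild type and 542 ± 88.8 CPM in Npas3-/-, and Pifo was the 1 member that rose with the correction.

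Across the 29 lists camera with a preset correlation of 0.01 called 3 without and 4 with the GC and length correction, and 0 in either fit with an estimated correlation. The latter setting rests on 2 residual degrees of freedom, and its smallest camera adjusted p was 0.944 without and 0.852 with the correction. Neural progenitor genes had an estimated correlation of -0.035 in the corrected fit, below the preset, and still went from 0.00469 to 0.852 by camera. The lost calls alone therefore say little about correlation between genes. The estimates, which rest on the same 2 residual degrees of freedom, were mostly above the preset. Without the correction they were 0.987 for mitochondrial-genome, 0.567 for autism and 0.143 for glycolysis and hypoxia genes. With it they were 0.754 for mitochondrial-genome, 0.355 for A1-type and 0.013 for autism genes. Where genes of a list move together, camera's p-values at the preset correlation are too small. Simulated data had 200 genes changed at random and a GC trend alike in both Npas3-/- libraries, with no trend in length or within genotypes. Their genes were drawn independently, so they do not test the correction on trends like those of the real libraries. On these data camera with the preset correlation called 3 of 29 lists without the correction and 0 with it. Without Npas3-/- replicate 1 it called 5 lists. By fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, 1 list passed, FGF signalling (adjusted p = 0.0374), and 26 passed for changes in either direction. Median, mean and test direction differed in sign for 9 lists, namely astrocyte markers, astrocyte-secreted synapse regulators, A2-type genes, interferon-stimulated genes, oligodendrocyte, endothelial and extracellular matrix genes, p53 targets and regional identity genes. Holding genes at 0 counts in a group at their bound left the list medians at 0.056 for oligodendrocyte, 0.10 for endothelial and -0.88 for glutamate, GABA and potassium genes, the values without it. Each of these lists held 1 such gene, whose bound stayed below the median, so the median could not move.

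Genes called in the same direction with and without the correction with at least 5 CPM on average were ranked by the corrected fold, a choice made after the data were seen. After Bc1, the largest corrected rises were those of Tm4sf1 (log2 fold change 3.74), Tspan7 (3.20), Mrpl17 (3.03), the BMP pseudoreceptor gene Bambi (3.03) and Saa3 (2.86), with the homeodomain gene Hopx at 2.67. Without the correction Tm4sf1 stood at 2.12, Tspan7 at 0.96, Mrpl17 at 0.83, Bambi at 1.27, Saa3 at 2.73 and Hopx at 2.29. The corrected rises of Tspan7, Mrpl17 and Bambi thus come in large part from the correction. It used their longest protein-coding transcripts, of 7067, 7300 and 5074 nt, and which transcripts were expressed was not tested. Among the largest corrected falls were those of Slc25a18, a mitochondrial glutamate carrier gene (-3.56), Lpo (-3.34), Fabp7 and C1ql3 (-3.10). Slc25a18 fell from 117 ± 32.3 to 16.6 ± 0.168 CPM, the GABA transporter gene Slc6a11 from 9.02 ± 2.69 to 1.37 ± 0.159 CPM, the glial adhesion gene Hepacam from 247 ± 31.5 to 42.2 ± 0.111 CPM and the potassium channel gene Kcnn3 from 58.2 ± 16.3 to 11.2 ± 3.20 CPM. Their transcripts had a GC content between 53.3% and 55.7%, in the range where the median fold change of all genes was above 0.

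Genes around Npas3 were compared with the rest of the genome. Within 20 Mb on chromosome 12, 71 of 168 tested genes changed (42.3%), 7 higher and 64 lower, against 33.0% elsewhere, an odds ratio of 1.49 (95% interval 1.08 to 2.04, p = 0.0133, two-sided Fisher's exact test). Genes are not independent replicates in this test. With windows of 5 Mb and of the whole chromosome the odds ratios were 1.55 (p = 0.0995) and 0.969 (p = 0.711, two-sided Fisher's exact tests). Egln3, the nearest tested gene downstream of Npas3, rose as given above, and Akap6, the nearest upstream (52699383 to 53155599), named after its values were seen, fell from 38.7 ± 15.4 to 2.70 ± 1.93 CPM. With the GC and length correction 20 of the 168 genes changed, 12 higher and 8 lower, the odds ratio was 1.44 (0.852 to 2.31, p = 0.128, two-sided Fisher's exact test) and Akap6 had a log2 fold change of -1.57.

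The sex-linked genes were read as a check of sample makeup. Kdm5d (1653, 3526, 214 and 244 counts in wild-type replicates 1 and 2 and Npas3-/- replicates 1 and 2), Ddx3y (269, 3992, 228 and 152), Uty (126, 1291, 93 and 70) and Eif2s3y (966, 3816, 212 and 216), all on the Y chromosome, had counts in every library. Kdm5d and Eif2s3y fell, with log2 fold changes of -3.29 and -3.27 (adjusted p = 0.0130 and 0.0235, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Ddx3y and Uty, at -3.27 and -2.90, did not pass. With the GC and length correction none of the 4 passed, at -1.04 for Kdm5d, -1.42 for Eif2s3y, -0.46 for Ddx3y and -0.053 for Uty. Xist had 0 counts in all 4, as did Tsix, which overlaps it on the other strand, so these zeros say nothing about the share of female cells where the counting left out reads shared by overlapping genes.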

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

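The correction for GC content and length, its combinations and the crossed block were chosen after the data were seen, and the other settings before. Leaving out each sample in turn moved the count of changed genes between 0 and 5832, of higher genes between 0 and 2005, of lower genes between 0 and 3827 and of genes changed at least 2-fold between 0 and 5679. The lone sample of a genotype was then assumed to vary like the other genotype, and the smaller number of samples is part of these settings. The 0 came without Npas3-/- replicate 2, where edgeR's quasi-likelihood test gave 5728 genes at an unadjusted p below 0.05, DESeq2 3635 calls and limma-voom 0. The Npas3 log2 fold change lay between -2.14 and -1.45, the list calls between 3 and 5, and the count after GC and length correction between 0 and 1746.

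Without a filter on low counts 3997 genes changed and 1018 were higher. DESeq2 called 8372 genes, 3524 of them higher, and limma-voom 6036. A test against a 1.5-fold change gave 2972 genes, 404 higher and 2568 lower, 2972 of them at least 2-fold. At an adjusted p below 0.01 edgeR called 0 genes, 0 higher, 0 lower and 0 at least 2-fold, the smallest adjusted p being 0.0130, with 9024 genes at an unadjusted p below 0.05. The first principal component held 69.2% over the 500 most variable genes. The replicate numbers were not shown to pair the samples: deviations of same-numbered samples correlated at r = -0.156 across genes. With the replicate block 2560 genes changed, 314 higher and 2246 lower, 2560 of them at least 2-fold. The crossed replicate block gave 7670 genes, 3336 higher.

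With the GC and length correction 1621 genes changed, 845 higher and 776 lower, 1254 at least 2-fold, and Npas3 stood at -0.66. Of the 6232 genes called without it 5155 were lost, and 15 were called in the opposite direction. The size of this loss depends on the test. In the corrected fit edgeR's quasi-likelihood test gave 5567 genes at an unadjusted p below 0.05, and DESeq2 called 3981 genes, against 8372 without the correction. The simulated GC trend shows that such a trend alone can produce calls, and which of the lost calls arose so was not tested. GC correction alone gave 1887 genes. With the correction and the replicate block edgeR called 0 genes (4359 at an unadjusted p below 0.05, 2545 by DESeq2). Under the correction 45 of the named genes kept their sign but lost their call, as did Npas3, and 6 changed sign: Stmn2 to 0.29, Olig1 to -0.70, Rarres2 to -0.094, Adamts5 to 0.38, Hmgcs1 to 0.083 and Spred1 to 0.23. Of these Rarres2, Adamts5, Hmgcs1 and Spred1 lost their call as well. With each sample left out Stmn2 lay between -0.86 and 0.41, positive without wild-type replicate 1.

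Camera called 0 lists with an estimated correlation, and 0 with the GC and length correction and an estimated correlation, settings limited by the 2 residual degrees of freedom. Fry called 1 by direction and 26 in either direction. With the filter of 5 CPM camera called 2 lists, glycolysis and hypoxia genes losing their call (adjusted p = 0.0627). List directions that turned were all of lists not called by camera. Under the correction these were, by camera adjusted p, phagocytosis (0.591), cell cycle (0.852), oligodendrocyte (0.507), endothelial (0.734), axon guidance (0.997), cholesterol (0.734), FGF (0.997), immediate early (0.734), p53 (0.276) and regional identity genes (0.276). With an estimated correlation too, the same lists had an adjusted p of 0.878, 0.997, 0.878, 0.951, 0.997, 0.997, 0.997, 0.951, 0.852 and 0.852. Endothelial genes turned with DESeq2 size factors (0.993), phagocytosis genes with no filter (0.888) and the replicate block (0.982), and microglia (0.914), fibroblast (0.634) and matrix genes (0.919) with the filter of 5 CPM. Of the microglia markers only Cd68 passed that filter. Leaving out samples turned directions too, with camera adjusted p from 0.699 to 0.988 for phagocytosis, 0.302 to 0.708 for interferon-stimulated, 0.0996 to 0.699 for cell cycle, 0.734 to 0.887 for endothelial, 0.407 to 0.881 for matrix, 0.284 to 0.823 for cholesterol, 0.513 to 0.887 for p53 and 0.506 to 0.824 for regional identity genes. The odds ratio around Npas3 was 1.55 at 5 Mb, 1.44 with the correction and 0.969 over the whole chromosome. For these and the other changes between settings the cause was not tested, apart from the smaller number of samples named above. Total depth was alike in all 4 libraries, although fewer genes had a count in the Npas3-/- libraries than in wild type. Low levels such as those of microglia markers are limited by their counts.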

Other observations

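The gene families and tests below were chosen after the data were seen, except the test on short transcripts, whose bound was written before its result. Of 77 cytosolic ribosomal protein genes 43 rose and 2 fell, with a median log2 fold change of 1.07 (camera adjusted p = 1.83e-13 over 8 families; adjusted p = 0.641 with an estimated correlation). A share of all counts was taken over an overlapping but different set, protein-coding genes with a symbol of Rpl or Rps followed by a digit. This share was 2.42% and 1.81% in wild-type replicates 1 and 2 and 3.24% and 4.04% in Npas3-/- replicates 1 and 2. Reads of the 77 genes may be shared with pseudogene copies. With the GC and length correction, which left 1621 changed genes in all, 17 of them rose and 2 fell (median 0.40). Mitochondrial ribosomal protein genes had 29 of 78 higher and 8 lower, with 20 and 5 after correction. Of 37 nuclear genes for complex I of the respiratory chain 13 rose and 1 fell, against 5 and 0 after correction. Proteasome subunit genes had 18 of 39 higher and 5 lower, with 8 and 0 after correction.

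Zinc finger genes with Zfp symbols went the other way. Of 353 tested 18 rose and 130 fell, with a median log2 fold change of -1.62 and a median GC content of 44.8% (camera adjusted p = 1.39e-05; adjusted p = 0.641 with an estimated correlation). After correction 4 rose and 20 fell, with a median of -0.39 (camera adjusted p = 0.00739, and 0.713 with an estimated correlation). Of 283 solute carrier genes 35 rose and 55 fell (13 and 12 after correction), of 54 replication-dependent histone genes 3 rose and 0 fell (2 and 0), and of 43 clustered protocadherin genes 0 rose and 1 fell (0 and 0), without a camera call (adjusted p = 0.946, 0.0524 and 0.912). Gm20716, a gene model that overlaps Adnp and Dpm1 on chromosome 2 (168180986 to 168230364), had 1788 and 2040 counts in wild type and 0 in both Npas3-/- libraries, at least 558-fold lower against a floor of 3 counts per library. Reads shared with Adnp and Dpm1 make its counts uncertain.

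Fold changes followed transcript GC content and length, and 2 explanations were weighed, a GC-dependent difference in library preparation or RNA quality and the loss of Npas3. For the first, libraries of the same genotype should differ along GC as well, and the smaller of the 2 rho values within a genotype was 0.359, so this explanation stays open and is a candidate for much of the trend. For the second, the median fold change spanned 3.46 on the log2 scale between the lowest and highest GC bins, against 2.13 between the wild-type libraries and 0.66 between the Npas3-/- libraries. The larger of these is 0.616 of the span between genotypes, which neither reaches that span nor falls far below it. With 2 libraries per genotype a part of the trend owed to Npas3 cannot be told apart from library differences.

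Npas3 counts were lower in Npas3-/-, and 2 explanations were weighed for the size of this fall. Among the 200 genes nearest in GC content and length, whose median log2 fold change was -1.40, the value of Npas3 lay at percentile 30.5, so the library trend may account for the fall as measured. A deletion that leaves other exons transcribed and counted stays open too: the Npas3-/- libraries kept 28.3% of the wild-type level, and gene counts do not show which exons the reads came from.

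Bc1 counts were higher in Npas3-/- by a log2 fold change of 7.55, and 2 explanations were weighed. Better recovery of short transcripts is argued against as the whole cause by 52 other nuclear genes of at most 300 nt, whose 95th percentile was 2.33 and whose highest value was 4.13. More neurons in the Npas3-/- cultures are argued against by the neuronal markers, of which Stmn3 had the highest log2 fold change, 1.60, and 10 of 15 were below 0. Genes of like length do not test other differences between the libraries, such as in how RNA was selected, which is not given. These differences, reads from repeat copies related to Bc1, and a rise of Bc1 transcription in Npas3-/- astrocytes stay open and were not tested.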
